A study of Homo sapiens with 120 samples.

How the data were processed

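Stranded libraries of polyadenylated RNA were sequenced by the authors from H1 human embryonic stem cells: 96 libraries of WT, KO and ΔATG cells at day 0 and over 5 days of 3 differentiation protocols, and 24 libraries of an overexpression arm. The deposited values are expected_counts, that is estimated counts per gene with decimals, for 62703 genes in 120 columns, and the deposited file is named as length scaled. Per the labels the genome build is GRCh38; the aligner, the quantifier and the annotation are not given in the sources used here. Gene positions were taken from GENCODE 29, which held 58279 of the 62703 identifiers. Each column was matched to a library by its description, and groups follow the labels for genotype or construct, protocol, and day or stage.

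Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table version 1.17.8; figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The 2 arms were fitted separately, one mean per group, which left 48 residual degrees of freedom in the differentiation arm and 12 in the overexpression arm. Genes with too few counts were removed by filterByExpr with the groups as design, leaving 25821 and 23300 genes that held at least 99.98% and 99.97% of the counts of each library. Libraries were scaled by TMM, with factors from 0.8575 to 1.114 and from 0.8748 to 1.137. Differences were tested with the edgeR quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment within each comparison, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F. Fold changes of groups without counts depend on the small count that edgeR adds, so such genes are given by CPM or counts. Comparisons over days 1 to 5, or over the 3 stages, average the contrasts of the single days or stages, and dependence on day or stage was tested by a joint F test of their differences. CPM values use the scaled totals, and their logarithm a prior count of 2.

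Gene lists, 31 in all, were written before the data were examined, as were the comparisons, the tests, the rule for naming genes and the alternatives in processing, apart from those said to be added later. They cover pluripotency, naive and 8-cell-like cells, primitive streak, definitive endoderm, mesoderm, amnion and trophoblast, neuroectoderm, neural crest and placode, endothelium and blood, fibroblast matrix, p53 targets, glycolysis, oxidative phosphorylation, sirtuins, targets of Wnt, BMP, Nodal, FGF and ERK, Notch and YAP, cell cycle, the integrated stress response, immediate early and heat shock genes, hypoxia, imprinted genes, chromosome 20q11, HOX clusters, mitochondrial transcripts, replication-dependent histones, ribosomal proteins and clustered protocadherins. Some genes belong to more than one list. Each list was tested against all other genes with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members were counted by calls over all tested genes and by calls adjusted over the list alone. The mean log2 CPM of a list was compared by two-sided exact permutation of libraries within days (7776 arrangements) or within stages (216 arrangements), adjusted over lists and comparisons. The genes named in each comparison are the 5 highest rises and 5 deepest falls among called genes with a mean log2 CPM of at least 1 and the same sign on every day or stage, the 2 highest and 2 deepest called members of each list, and LNCPRESS1 with its neighbours. List members given only by their CPM were chosen after their values were seen.

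Both edited lines share the WT libraries and all constructs share the vector, which alone makes fold changes correlate. Correlations between comparisons were therefore set beside 3 simulations of unchanged groups with the same shared controls. They were also set beside the overlap of independent calls and values with control libraries a for one comparison and b for the other. The averaged comparisons were also tested on 100 splits of the same libraries within days or stages. Libraries of one letter deviated together at day 0 and in BMP4. There the differences b minus a correlated above 0.1 in 18 of 18 pairs of groups (0.179 to 0.743). SMADi had 0 of 15 such pairs, Endo 1 of 15 and overexpression 4 of 18, those 4 all late. Middle vector and ΔATG had -0.388. The labels name no shared batch, so the pairing comes from the values. At day 0 and in BMP4 a count with a block for the letter stands beside counts it moves over 1.5 times. The pipeline was tested on simulated data with 100 changed genes per size among 25427. At day 0 it recovered 38% of log2 changes of 0.5 and 81% of 1, with 37 unchanged genes called. Days 1 to 5 of BMP4 gave 88% and 100%, with 14. Whether real day 0, where letters deviate together, has so few false calls was not tested.

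Alternatives tried were DESeq2 size factors, no filter on low counts, a block for the replicate letter, voom with sample weights, the DESeq2 test, a fit of only the libraries compared, leaving out each library in turn, an estimated correlation for list tests, prior counts of 0.5 and 5, and WT or vector libraries split by letter. Added after seeing the data were the overexpression averages without the middle stage, without the early stage and with the early labels of lncPRESS1 and lncSIRP exchanged, and in BMP4 the agreement of the lines from libraries of one letter each. When a library is left out its group has 1 library, which is assumed to vary like the other groups. Total counts, given under Results, set the precision. PCR duplicates cannot be told from independent molecules. Splicing, variants and the edited sequence were not analysed because only counts per gene were available.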

Results

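RNA was measured in 120 libraries of H1, an established human embryonic stem cell line. The gene under study is LNCPRESS1 (lncPRESS1, ENSG00000232301), a long non-coding RNA gene of pluripotent cells. The differentiation arm holds 96 libraries in 48 groups: unedited (WT), knockout (KO) and ΔATG cells at day 0 and on each of days 1 to 5 of 3 protocols. The protocols are BMP4 for mesoderm, SMAD inhibition for neuroectoderm (SMADi) and a commercial kit for definitive endoderm (Endo). ΔATG is, from its name, lncPRESS1 without a start codon. The overexpression arm holds 24 libraries in 12 groups: an empty vector, lncPRESS1, lncPRESS1 ΔATG and lncSIRP, each at an early, a middle and a late stage. What lncSIRP is, which days the stages stand for and how many clones carry each edit are not given in the sources used here, so genotype and clone cannot be separated. Each group has 2 libraries, a and b. They are not stated to be separate cultures, so the p-values measure spread between these libraries, which can be technical. Total counts per library ran from 38298440 to 71220396 in the differentiation arm, with 25832 to 29131 genes above 0, and from 40113672 to 65466258 in the overexpression arm, with 26026 to 28324 genes above 0. Log2 fold changes are given ± SE, and counts scaled to library size as CPM ± SD, with n = 2 libraries per group. A gene is said to rise or fall where its adjusted p passed the threshold, camera calls given without a second p also held with an estimated correlation, and a direction not named for a list had no member called.

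The first question was how far each edit changed the RNA of LNCPRESS1, which lies on chromosome 7 from 101299578 to 101301346. At day 0 it measured 31 ± 13.5 CPM in WT, 9.39 ± 5.36 in KO and 44.2 ± 12.7 in ΔATG. It fell in KO (-1.70 ± 0.22, adjusted p = 2.22e-07) without being lost, and was not called in ΔATG (0.52 ± 0.20, adjusted p = 0.122). Over the 5 days of BMP4 it fell in KO (-1.27 ± 0.11, adjusted p = 1.14e-14) and again was not called in ΔATG (-0.07 ± 0.10, adjusted p = 0.719). In SMADi it fell in both KO (-3.47 ± 0.23, adjusted p = 7.72e-20) and ΔATG (-3.61 ± 0.29, adjusted p = 1.87e-16). The fall in KO at day 0 was not called in a fit of the 4 libraries compared. KO was already called lower at day 1 of SMADi (-1.14 ± 0.20, adjusted p = 2.57e-05). The fall in ΔATG was not called at day 1 (-0.44 ± 0.20, adjusted p = 0.175) or day 2 (-0.20 ± 0.23, adjusted p = 0.655) and was called at day 3 (-2.16 ± 0.35, adjusted p = 1.23e-06). In WT itself the RNA fell in SMADi from 53.7 ± 0.959 CPM at day 1 to 1.65 ± 0.0639 at day 5, and in BMP4 to 13.6 ± 0.988 at day 5. In Endo it measured 1.35 ± 0.427 CPM in WT at day 1 and was called in neither line over the 5 days (KO -0.45 ± 0.91, adjusted p = 0.891; ΔATG 1.05 ± 0.64, adjusted p = 0.22). Of its neighbours, EMSLR, a non-coding gene 7 kb away, fell in SMADi in both KO (-2.14, adjusted p = 1.81e-28) and ΔATG (-1.37, adjusted p = 4.92e-22).

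**Figure D1:**
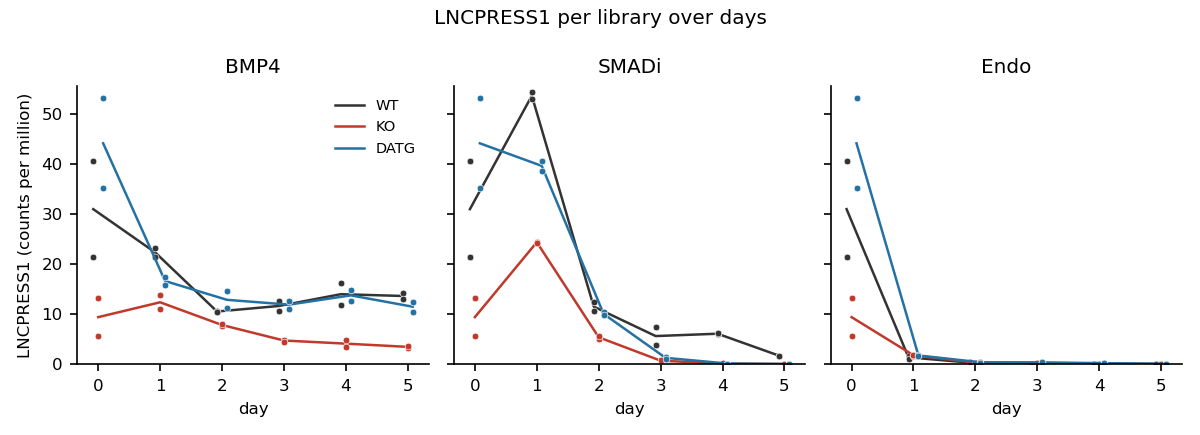
LNCPRESS1 in CPM against day of differentiation in BMP4, SMADi and Endo, with points for libraries and lines for group means of WT, KO and ΔATG. KO lies below WT at day 0 (9.39 against 31 CPM) and through BMP4, while in SMADi KO is called lower on each day and ΔATG from day 3.

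In WT cells each protocol raised marker genes of the germ layer it is named for. With BMP4, HAND1, a transcription factor of lateral and extra-embryonic mesoderm, rose from 0.0339 ± 0.0479 CPM at day 0 to 224 ± 22.7 at day 5, and TBXT, the primitive streak factor, peaked at 151 ± 6.48 CPM on day 2. By day 5 of BMP4, 21 of 24 tested mesoderm genes rose and 0 fell, and 20 of 22 tested genes of amnion and trophoblast rose and 2 fell. In SMADi, PAX6, which marks neuroectoderm, rose from 0.145 ± 0.0816 to 26.7 ± 2.35 CPM at day 4, and 24 of 26 tested neuroectoderm genes rose and 0 fell. In Endo, CER1, a secreted antagonist of Nodal made by endoderm, reached 11660 ± 301 CPM and SOX17 423 ± 1.14 CPM at day 5, and 19 of 19 tested endoderm genes rose and 0 fell. The stem cell factor SOX2 measured 350.3 ± 37.1 CPM at day 0, 0.107 ± 0.00999 at day 5 of Endo, 135 ± 16.6 in BMP4 and 642 ± 5.39 in SMADi. Against day 0, 11629 genes were called at day 5 of BMP4, 13824 in SMADi and 16374 in Endo. In Endo 1 of 23 tested cell cycle genes rose and 19 fell, and in SMADi 2 of 22 tested glycolysis genes rose and 18 fell.

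At day 0 the question was which genes differ between edited and unedited cells. NANOG, a core factor of the pluripotent state, measured 78 ± 9.54 CPM in WT, 38.7 ± 31.2 in KO and 85.7 ± 33.6 in ΔATG, and fell in KO (-1.0 ± 0.27). Among genes that respond to Nodal, FGF and BMP, LEFTY1 (-1.85 ± 0.36), NODAL (-0.86 ± 0.22), the ERK phosphatase DUSP6 (-1.29 ± 0.30) and SMAD7 (-1.20 ± 0.23) fell in KO. CFLAR, an inhibitor of caspase 8, rose (2.33 ± 0.22), as did the orphan receptor GPR50 (1.67 ± 0.17). In the FGF and ERK list 1 of 14 tested members rose, 7 fell and 6 were not called (1 rose and 7 fell adjusted over the list alone, camera adjusted p = 2e-05, and adjusted p = 0.197 with an estimated correlation). In the pluripotency list 8 of 24 tested members fell and 16 were not called (1 rose and 8 fell adjusted over the list alone, camera adjusted p = 0.00619, and adjusted p = 0.654 with an estimated correlation). In the Nodal list 5 of 11 tested members fell and 6 were not called (1 rose and 5 fell adjusted over the list alone, camera adjusted p = 0.00638, and adjusted p = 0.193 with an estimated correlation). In the BMP list 4 of 13 tested members fell and 9 were not called (4 fell adjusted over the list alone, camera adjusted p = 0.00358, and adjusted p = 0.193 with an estimated correlation). For neuroectoderm 5 of 26 tested members fell and 21 were not called (5 fell adjusted over the list alone, camera adjusted p = 0.017, and adjusted p = 0.197 with an estimated correlation), and camera with the replicate block gave an adjusted p = 0.0624. In all, 1263 genes were called in KO, 480 higher and 783 lower. This count rests on single libraries: it was 272 without KO library b, 274 without WT library a, 1934 without WT library b and 3262 without KO library a. It was 3188 with the replicate block, 77 with voom and 3 in a fit of the 4 libraries compared, where none of the changes named here was called. With voom NANOG, LEFTY1, NODAL, DUSP6 and SMAD7 were not called. Without WT library a NANOG (-1.12), NODAL (-0.90), DUSP6 (-1.21) and SMAD7 (-0.93) were not called. Without KO library a the change was -2.23 for NANOG, -3.37 for LEFTY1, -1.60 for NODAL and -2.44 for DUSP6. Without WT library b NANOG (-0.87) was not called. Without KO library b NANOG (-0.36), LEFTY1 (-1.22), NODAL (-0.43), DUSP6 (-0.69) and SMAD7 (-0.84) were not called.

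In ΔATG at day 0 the genes that fell included targets of p53, and those that rose included factors of the integrated stress response. CDKN1A, the p53 target that stops the cell cycle, fell by 1.40 ± 0.20 from 16.1 ± 7.61 CPM in WT, and BTG2 fell by 0.95 ± 0.20. ATF5, a factor of the integrated stress response, measured 28.6 ± 20.4 CPM in WT and 102 ± 20.1 in ΔATG (1.84 ± 0.25), and TRIB3, a pseudokinase of the same response, rose by 1.51 ± 0.27. The glycolysis regulator PFKFB3 (-0.93 ± 0.21), the endoderm receptor CXCR4 (-1.46 ± 0.28), GDF3 (-1.15 ± 0.18) and the maternally expressed imprinted genes H19 (-2.26 ± 0.27) and MEG3 (-5.31 ± 0.56) fell, and the histone gene H2AC6 rose (1.94 ± 0.28). In the p53 list 10 of 24 tested members fell and 14 were not called (13 fell adjusted over the list alone, camera adjusted p = 1.07e-09). In the imprinted list 1 of 20 tested members rose, 3 fell and 16 were not called (1 rose and 5 fell adjusted over the list alone, camera adjusted p = 0.00172). In the stress response list 7 of 14 tested members rose and 7 were not called (9 rose adjusted over the list alone, camera adjusted p = 4.42e-10, and adjusted p = 0.09 with an estimated correlation). In glycolysis 6 of 22 tested members fell and 16 were not called (14 fell adjusted over the list alone, camera adjusted p = 4.42e-10, and adjusted p = 0.208 with an estimated correlation). In the cell cycle list 5 of 23 tested members fell and 18 were not called (5 fell adjusted over the list alone, camera adjusted p = 0.00128, and adjusted p = 0.208 with an estimated correlation). The direct test of ΔATG against KO gave the same direction for p53 targets. Of that list, 1 of 24 tested members rose, 9 fell and 14 were not called (1 rose and 10 fell adjusted over the list alone, camera adjusted p = 7.85e-12), with NANOG (1.14 ± 0.27), ID1 (1.05 ± 0.15) and DUSP6 (1.30 ± 0.30) higher in ΔATG than in KO. There were 1420 calls in ΔATG, 593 higher and 827 lower, and 1050 between the edited lines, 556 higher and 494 lower in ΔATG. The ΔATG count was 150 without WT library a, 713 without ΔATG library a and 2392 without WT library b, and the count between the lines 155 without KO library b, 169 without ΔATG library a, 1966 without ΔATG library b and 3476 without KO library a. The counts were 2804 and 2661 with the replicate block, 248 and 118 with voom, and 2 and 3 in a fit of the libraries compared, where none of the changes named here was called. With voom BTG2, PFKFB3 and CXCR4 were not called against WT, nor NANOG and DUSP6 against KO. In ΔATG against WT, without WT library a BTG2 (-0.47), TRIB3 (0.97), PFKFB3 (-0.24), CXCR4 (-0.61) and GDF3 (-0.78) were not called, and the change was -0.81 for CDKN1A. Without ΔATG library a BTG2 (-0.86) and PFKFB3 (-0.87) were not called, and the change was 1.17 for H2AC6. Without WT library b the change was 2.85 for ATF5 and 2.37 for TRIB3. In ΔATG against KO, without KO library a the change was 2.37 for NANOG and 2.45 for DUSP6. Without ΔATG library a NANOG (0.68) and DUSP6 (0.17) were not called. Without KO library b NANOG (0.50) and DUSP6 (0.70) were not called.

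With BMP4 the question was whether the edited lines form mesoderm as WT does. KO cells made less of the primitive streak and mesoderm programme and expressed more of the stem cell programme. TBXT at day 2 measured 21.8 ± 0.830 CPM in KO against 151 ± 6.48 in WT, and HAND1 at day 5 67.5 ± 17.9 against 224 ± 22.7. SOX2 at day 5 measured 376 ± 52.5 CPM in KO against 135 ± 16.6 in WT and rose over the 5 days (0.87 ± 0.05), as did PRDM14 (0.86 ± 0.10) and the forebrain genes FEZF1 (1.32 ± 0.15) and NPTX1 (1.96 ± 0.12). Among streak genes EVX1 fell by 2.28 ± 0.11 and the apelin receptor APLNR fell by 2.11 ± 0.14. In that list, 15 of 16 tested members fell and 1 was not called (16 fell adjusted over the list alone, camera adjusted p = 5.81e-18). Of the mesoderm list, with FOXF1 (-2.45 ± 0.30) and BMP5 (-2.21 ± 0.45), 20 of 24 tested members fell and 4 were not called (21 fell adjusted over the list alone, camera adjusted p = 2.26e-23). Amnion and trophoblast genes, with CDX2 (-2.51 ± 0.19) and TFAP2B (-2.23 ± 0.43), fell too. In that list, 1 of 22 tested members rose, 19 fell and 2 were not called (1 rose and 19 fell adjusted over the list alone, camera adjusted p = 2.86e-15). Direct targets of BMP signalling, with MSX1 (-1.86 ± 0.12) and GATA2 (-1.51 ± 0.11), were lower. In that list, 13 of 13 tested members fell (13 fell adjusted over the list alone, camera adjusted p = 1.46e-14). Of the pluripotency genes, 17 of 24 tested members rose, 1 fell and 6 were not called (17 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.04e-08). Without WT day 1 library b TFAP2B (-1.71) was not called.

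Among targets of other signals of the streak, the Wnt and Nodal lists were lower in KO. For Wnt targets, with LGR5 (-2.26 ± 0.31) and SP5 (-1.53 ± 0.07), 2 of 14 tested members rose, 10 fell and 2 were not called (2 rose and 10 fell adjusted over the list alone, camera adjusted p = 4.24e-07). For Nodal targets, with FGF17 (-1.49 ± 0.12) and CER1 (-1.41 ± 0.09), 2 of 11 tested members rose and 9 fell (2 rose and 9 fell adjusted over the list alone, camera adjusted p = 0.000316). For FGF and ERK targets, with DUSP6 (-1.18 ± 0.13), 9 of 14 tested members fell and 5 were not called (9 fell adjusted over the list alone, camera adjusted p = 2.78e-05, and adjusted p = 0.109 with an estimated correlation). In the endoderm list, with SOX17 (-1.93 ± 0.12), 3 of 19 tested members rose, 14 fell and 2 were not called (3 rose and 15 fell adjusted over the list alone, camera adjusted p = 5.32e-10). In the HOX clusters 8 of 13 tested members fell and 5 were not called (8 fell adjusted over the list alone, camera adjusted p = 1.83e-14). Collagen and other matrix genes, with COL5A1 (-1.13 ± 0.06) and COL1A2 (-0.75 ± 0.04), fell. In that list, 7 of 13 tested members fell and 6 were not called (10 fell adjusted over the list alone, camera adjusted p = 3.27e-06). Ribosomal protein genes went the other way. Of that list, 33 of 82 tested members rose, 1 fell and 48 were not called (43 rose and 1 fell adjusted over the list alone, camera adjusted p = 2e-08, and adjusted p = 0.447 with an estimated correlation). SIRT1, a deacetylase, rose (0.46 ± 0.09). In the sirtuin list 2 of 7 tested members rose and 5 were not called (2 rose adjusted over the list alone, camera adjusted p = 0.206). By exact two-sided permutation of libraries within days, the mean log2 CPM of the mesoderm list in KO minus WT was -1.43 (exact permutation adjusted p = 0.00167, higher on 0 of 5 days), and of the pluripotency list 0.27 (exact permutation adjusted p = 0.0057, higher on 5 of 5 days). The smallest adjusted p seen was 0.00167. In KO, 7404 genes were called, 3426 higher and 3978 lower, of which 973 changed at least 2-fold. By day, 327 genes were called at day 1, 2117 at day 2, 2547 at day 3, 4022 at day 4 and 5746 at day 5, and the effect varied with day for 2684 genes. In a fit of the libraries compared the days gave 12, 435, 185, 2 and 2582 calls, and 377 genes varied with day. With the replicate block days 1, 3 and 4 gave 718, 3995 and 6158, and 5406 genes varied with day, against 1485 with voom.

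ΔATG moved in the same directions with BMP4, and p53 targets fell beside the mesoderm genes. HAND1 at day 5 measured 135 ± 18.6 CPM and TBXT at day 2 72.6 ± 32.5. CDKN1A at day 5 measured 42 ± 5.58 CPM against 202 ± 37.6 in WT (-1.73 ± 0.08 over the 5 days), and GDF15, a stress cytokine, fell by 1.67 ± 0.11. In the p53 list 20 of 24 tested members fell and 4 were not called (21 fell adjusted over the list alone, camera adjusted p = 2.22e-23). Among streak genes FGF17 (-1.53 ± 0.14) and EVX1 (-1.36 ± 0.10) fell. In that list, 14 of 16 tested members fell and 2 were not called (14 fell adjusted over the list alone, camera adjusted p = 5.3e-15). In the mesoderm list 15 of 24 tested members fell and 9 were not called (19 fell adjusted over the list alone, camera adjusted p = 1.38e-13), and in the BMP list, with MSX1 (-0.91 ± 0.10), 9 of 13 tested members fell and 4 were not called (9 fell adjusted over the list alone, camera adjusted p = 2.88e-06). FOXA2 (-1.40 ± 0.12) and PRDM1 (-1.34 ± 0.11) fell in the endoderm list. Of that list, 1 of 19 tested members rose, 13 fell and 5 were not called (2 rose and 14 fell adjusted over the list alone, camera adjusted p = 2.01e-09). CDX2 fell (-1.38 ± 0.16) among amnion and trophoblast genes. Of that list, 2 of 22 tested members rose, 11 fell and 9 were not called (2 rose and 13 fell adjusted over the list alone, camera adjusted p = 3.97e-06). SOX2 (0.61 ± 0.05), PRDM14 (0.92 ± 0.10), NPTX1 (1.71 ± 0.12) and FEZF1 (1.41 ± 0.14) rose. In the pluripotency list 15 of 24 tested members rose, 2 fell and 7 were not called (16 rose and 2 fell adjusted over the list alone, camera adjusted p = 6.34e-11). There were 4381 calls, 2114 higher and 2267 lower, with 240, 630, 1445, 1321 and 2869 on days 1 to 5. In a fit of the libraries compared there were 2608, with 3, 9, 2, 3 and 852 by day, and the replicate block gave 417, 1264, 2957 and 2474 on days 1 to 4. The effect varied with day for 587 genes, a count that was 376 without WT day 5 library b, 387 without ΔATG day 5 library b and 818 without WT day 4 library b. It was 20 in a fit of the libraries compared, 281 with voom, 955 with the DESeq2 test and 1465 with the replicate block.

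Compared directly, ΔATG expressed more of the mesoderm programme than KO with BMP4. TBXT (1.01 ± 0.08), ISL1 (1.35 ± 0.10), CDX2 (1.13 ± 0.21) and HEY1 (1.17 ± 0.10) were higher in ΔATG, and CDKN1A was lower (-1.08 ± 0.08). Of the mesoderm genes, 16 of 24 tested members rose and 8 were not called (17 rose adjusted over the list alone, camera adjusted p = 1.02e-16). For BMP targets 12 of 13 tested members rose and 1 was not called (12 rose adjusted over the list alone, camera adjusted p = 9.17e-13). For amnion and trophoblast 16 of 22 tested members rose and 6 were not called (17 rose adjusted over the list alone, camera adjusted p = 4.96e-15). For p53 targets 1 of 24 tested members rose, 12 fell and 11 were not called (1 rose and 16 fell adjusted over the list alone, camera adjusted p = 2.21e-13). This comparison called 3508 genes, 2238 higher and 1270 lower in ΔATG, and 6175 with the replicate block and 1669 in a fit of the libraries compared.

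In SMADi the question was whether the edited lines form neuroectoderm as WT does. Both lines had less NANOG and UTF1 than WT at day 1 and more PAX6 at day 4. NANOG at day 1 measured 172 ± 14.7 CPM in WT, 44.3 ± 0.645 in KO and 43 ± 0.0364 in ΔATG, and UTF1, a chromatin factor of stem cells, 110.3 ± 0.705, 8.14 ± 0.740 and 10.9 ± 1.53. NANOG at day 0 had measured 78 ± 9.54 CPM in WT and 38.7 ± 31.2 in KO, so the gap at day 1 includes a rise in WT. PAX6 at day 4 measured 26.7 ± 2.35 CPM in WT, 227 ± 3.37 in KO and 219.6 ± 0.556 in ΔATG. SIX3, which marks the anterior neural plate, measured 357 ± 14 CPM in WT at day 4, 3.69 ± 0.184 in KO and 10.9 ± 1.61 in ΔATG, so the neural list moved both ways. In KO, POU3F2 (3.85 ± 0.37) and PAX6 (2.86 ± 0.32) rose and SIX3 (-4.05 ± 0.13) fell. In that list, 12 of 26 tested members rose, 8 fell and 6 were not called (13 rose and 8 fell adjusted over the list alone, camera adjusted p = 0.0455, and adjusted p = 0.18 with an estimated correlation). In ΔATG, POU3F2 (3.86 ± 0.37) and PAX6 (2.76 ± 0.31) rose and ZIC1 (-4.45 ± 0.15) fell. In that list, 13 of 26 tested members rose, 8 fell and 5 were not called (14 rose and 8 fell adjusted over the list alone, camera adjusted p = 0.0261, and adjusted p = 0.17 with an estimated correlation). In the pluripotency list of KO 3 of 24 tested members rose, 18 fell and 3 were not called (3 rose and 18 fell adjusted over the list alone, camera adjusted p = 1.29e-10), and of ΔATG 3 of 24 tested members rose, 18 fell and 3 were not called (4 rose and 18 fell adjusted over the list alone, camera adjusted p = 4.45e-10). SOX2, which neural progenitors also express, measured 642 ± 5.39, 659.8 ± 15.3 and 709.7 ± 5.96 CPM at day 5 in WT, KO and ΔATG.

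Several Nodal and FGF targets fell in SMADi. FGF17 fell in KO (-4.50 ± 0.20) and ΔATG (-4.12 ± 0.19), as did ETV4, a factor induced by FGF (-3.39 ± 0.08 and -2.91 ± 0.07). In the Nodal list of KO 6 of 11 tested members fell and 5 were not called (6 fell adjusted over the list alone, camera adjusted p = 1.61e-05). In that of ΔATG 6 of 11 tested members fell and 5 were not called (6 fell adjusted over the list alone, camera adjusted p = 8.26e-05). For FGF and ERK in KO 2 of 14 tested members rose, 11 fell and 1 was not called (2 rose and 11 fell adjusted over the list alone, camera adjusted p = 1.7e-07, and adjusted p = 0.0776 with an estimated correlation). In ΔATG 2 of 14 tested members rose, 10 fell and 2 were not called (2 rose and 11 fell adjusted over the list alone, camera adjusted p = 3.26e-06, and adjusted p = 0.144 with an estimated correlation). HHEX fell in KO (-4.62 ± 0.14) and ΔATG (-4.10 ± 0.13). Among amino acid response genes ASNS fell in both (-2.05 ± 0.13 and -1.70 ± 0.13). In the stress response list of KO 12 of 14 tested members fell and 2 were not called (12 fell adjusted over the list alone, camera adjusted p = 4.53e-06, and adjusted p = 0.18 with an estimated correlation). The lactate transporter SLC16A3 fell in both (-1.83 ± 0.13 and -1.42 ± 0.13). In the glycolysis list of KO 1 of 22 tested members rose, 18 fell and 3 were not called (1 rose and 18 fell adjusted over the list alone, camera adjusted p = 7.6e-08, and adjusted p = 0.18 with an estimated correlation). Ribosomal protein genes fell in KO, with RPL8 (-0.38 ± 0.04). In that list, 1 of 82 tested members rose, 72 fell and 9 were not called (1 rose and 74 fell adjusted over the list alone, camera adjusted p = 1.55e-07, and adjusted p = 0.497 with an estimated correlation). The contractile genes ACTA2 (1.98 ± 0.08 in KO, 1.65 ± 0.08 in ΔATG) and TAGLN (1.57 ± 0.06, 1.75 ± 0.06) rose. In the matrix list of KO 9 of 13 tested members rose and 4 were not called (9 rose and 1 fell adjusted over the list alone, camera adjusted p = 4.49e-05). The YAP target CCN2 rose by 1.17 ± 0.08 in KO and 1.31 ± 0.08 in ΔATG. In that list of KO, 6 of 10 tested members rose and 4 were not called (6 rose adjusted over the list alone, camera adjusted p = 0.000133, and adjusted p = 0.18 with an estimated correlation).

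By count, SMADi showed the most calls of the 3 protocols, 11781 in KO (5434 higher, 6347 lower) and 11660 in ΔATG (5398 higher, 6262 lower). NRIP3 (2.93 ± 0.08 in KO, 2.79 ± 0.08 in ΔATG), ZEB2 (2.79 ± 0.38, 2.82 ± 0.38) and VAT1L (2.71 ± 0.05, 2.52 ± 0.05) were among the highest rises in both lines. By day, KO had 2232, 3783, 7892, 9325 and 9084 calls on days 1 to 5, and ΔATG 2652, 4336, 7332, 8864 and 8330. The edited lines differed from each other for 275 genes, 153 higher and 122 lower in ΔATG, and for 462 with the DESeq2 test, 693 with voom and 581 in a fit of the libraries compared. p53 targets were lower in ΔATG than in KO, with BTG2 (-0.49 ± 0.08) and PHLDA3 (-0.44 ± 0.11). In that list, 6 of 24 tested members fell and 18 were not called (11 fell adjusted over the list alone, camera adjusted p = 2.14e-13). Without KO day 1 library a PHLDA3 (-0.43) was not called. Without KO day 5 library a PHLDA3 (-0.41) was not called. Without ΔATG day 5 library b PHLDA3 (-0.33) was not called.

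In Endo the question was whether the edited lines form definitive endoderm as WT does. Both lines did express endoderm genes: SOX17 at day 5 measured 423 ± 1.14 CPM in WT, 409.8 ± 9.37 in KO and 356 ± 3.51 in ΔATG. GATA4, an endoderm factor, measured 209.6 ± 0.862 CPM in WT at day 2, 156 ± 3.10 in KO and 82.6 ± 10.7 in ΔATG, and fell over the 5 days in KO (-0.37 ± 0.07). POU5F1, the stem cell factor OCT4, was higher in both lines, at day 5 with 18.6 ± 0.758 CPM in KO and 41.9 ± 0.0896 in ΔATG against 8.57 ± 0.192 in WT, a rise of 0.48 ± 0.04 in KO and 1.24 ± 0.04 in ΔATG over the 5 days. In the endoderm list of KO, with FOXA1 (0.93 ± 0.14) higher and FOXQ1 (-1.32 ± 0.11) lower, 6 of 19 tested members rose, 2 fell and 11 were not called (6 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.196). Cell cycle genes fell in KO by small amounts, with E2F1 (-0.34 ± 0.05) and PCNA (-0.32 ± 0.04). In that list, 17 of 23 tested members fell and 6 were not called (20 fell adjusted over the list alone, camera adjusted p = 4.92e-13). Streak and mesoderm genes fell in KO, with TBXT (-0.83 ± 0.11) and MSX2 (-1.10 ± 0.09). In the mesoderm list 1 of 24 tested members rose, 10 fell and 13 were not called (1 rose and 11 fell adjusted over the list alone, camera adjusted p = 2.67e-05). In the streak list 8 of 16 tested members fell and 8 were not called (11 fell adjusted over the list alone, camera adjusted p = 0.00281, and adjusted p = 0.0791 with an estimated correlation). Protocadherins of the clusters fell, with PCDHB5 (-3.29 ± 0.09). In those clusters, 15 of 54 tested members fell and 39 were not called (1 rose and 15 fell adjusted over the list alone, camera adjusted p = 9.2e-08). KO had 3820 calls, 1745 higher and 2075 lower, with GPR50 (2.12 ± 0.21) among the highest rises and IRX1 (-4.81 ± 0.20) and PURPL (-3.53 ± 0.13) among the largest falls, and 847, 1201, 956, 1039 and 1416 on days 1 to 5. In a fit of the libraries compared days 1, 3 and 4 gave 231, 535 and 312.

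ΔATG differed from WT more widely in Endo, with 8738 calls, 4296 higher and 4442 lower. SOX2 rose (2.06 ± 0.13), as did the hormone APELA (3.33 ± 0.42), the vesicle protein SYT4 (2.88 ± 0.43) and the surface protein THY1 (1.48 ± 0.09). Of the pluripotency genes, 11 of 24 tested members rose, 3 fell and 10 were not called (11 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.00434, and adjusted p = 0.354 with an estimated correlation). MESP1, a mesoderm factor of the streak, measured 74.6 ± 18.6 CPM in WT at day 1, 43.8 ± 3.32 in KO and 8.03 ± 1.31 in ΔATG (-2.58 ± 0.36 over the 5 days). NKX2-5 (-3.89 ± 0.36) and MSX2 (-1.82 ± 0.10) fell too. Of the mesoderm genes, 14 of 24 tested members fell and 10 were not called (1 rose and 14 fell adjusted over the list alone, camera adjusted p = 1.42e-06). CER1 fell by 0.56 ± 0.07, and in the endoderm list, with FOXA1 (1.39 ± 0.18) higher and LGR5 (-1.42 ± 0.16) lower, 6 of 19 tested members rose, 9 fell and 4 were not called (6 rose and 9 fell adjusted over the list alone, camera adjusted p = 0.489). The YAP target ANKRD1 fell by 2.02 ± 0.20. In that list, 2 of 10 tested members rose, 7 fell and 1 was not called (2 rose and 8 fell adjusted over the list alone, camera adjusted p = 0.0017, and adjusted p = 0.285 with an estimated correlation). Calls on days 1 to 5 numbered 3767, 3544, 4100, 3824 and 4701, and 2477 and 1922 on days 1 and 2 in a fit of the libraries compared. Between the lines 4741 genes were called, 2250 higher and 2491 lower in ΔATG, with SOX2 (2.05 ± 0.12) and the cell cycle gene CENPF (0.45 ± 0.07) higher. In the cell cycle list of that comparison 17 of 23 tested members rose and 6 were not called (19 rose adjusted over the list alone, camera adjusted p = 5e-11).

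**Figure D2:**
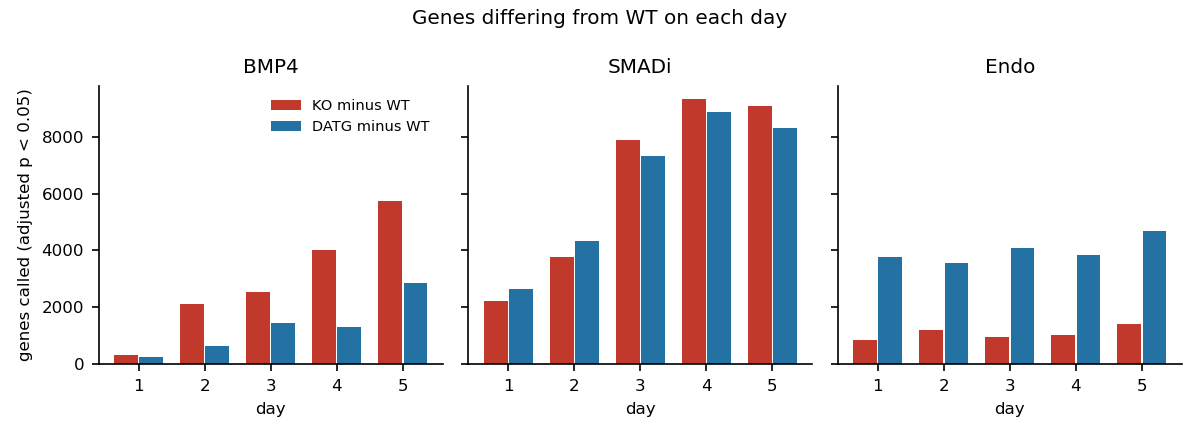
Number of genes called at each day against WT in BMP4, SMADi and Endo, for KO and ΔATG. SMADi calls climb from 2232 in KO at day 1 to 9325 at day 4, KO exceeds ΔATG on each day of BMP4, and ΔATG exceeds KO on each day of Endo.

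The effect of each edit was compared between protocols by testing the difference. Relative to WT, the pluripotency list in KO lay higher in BMP4 than in SMADi by a median of 1.16 (camera adjusted p = 8.88e-16, 0.00379 with an estimated correlation, 22 of 24 members differing on their own). In ΔATG it lay higher by 1.11 (camera adjusted p = 1.77e-17, 0.00274 with an estimated correlation, 21 of 24 members differing on their own). Mesoderm genes in KO were lower in BMP4 than in Endo relative to WT, by -1.02 (camera adjusted p = 5.04e-10, 0.000333 with an estimated correlation, 11 of 24 members differing on their own). The loss of p53 targets in ΔATG was deeper in BMP4 than in Endo, by -0.31 (camera adjusted p = 9.18e-05, 0.0401 with an estimated correlation, 12 of 24 members differing on their own), and deeper than in SMADi, by -0.41 (camera adjusted p = 9.22e-06, 0.0153 with an estimated correlation, 15 of 24 members differing on their own).

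**Figure D3:**
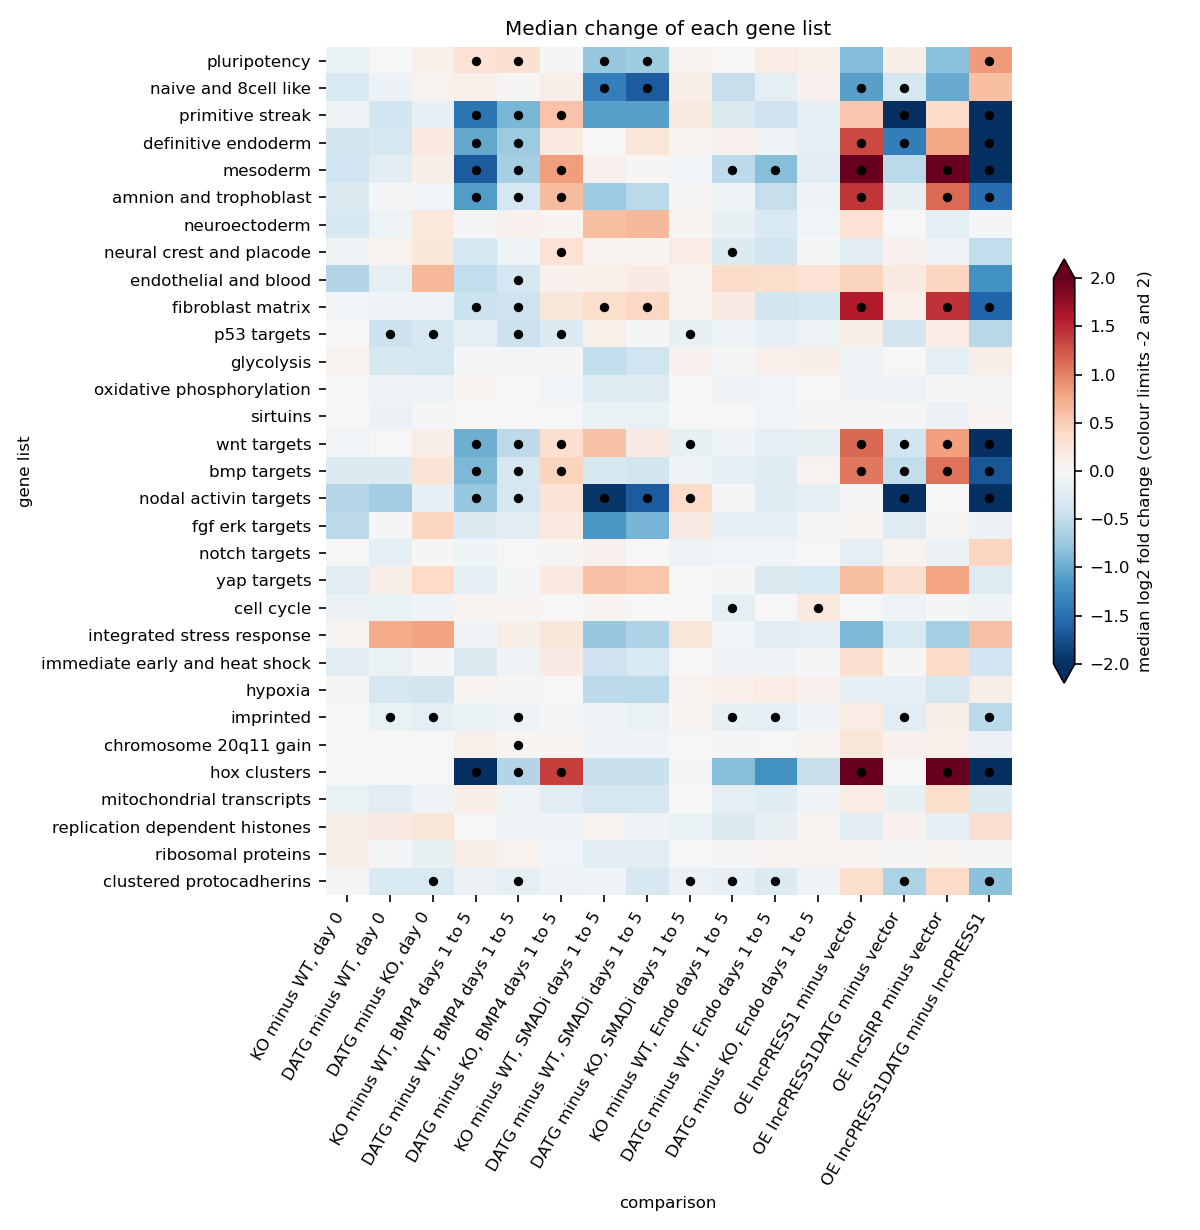
Median log2 fold change of each of the 31 gene lists (vertical) in each of 16 comparisons (horizontal), on a colour scale from -2 to 2, with a black dot where camera passed its threshold with both the preset and the estimated correlation. Mesoderm, streak and BMP lists are low in BMP4 for KO and ΔATG, and streak and Nodal lists are low with overexpressed lncPRESS1 ΔATG.

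How far KO and ΔATG changed the same genes was measured across genes, which are not independent replicates, and both comparisons share the WT libraries. In BMP4 the fold changes correlated at r = 0.639 over 13799 genes, where unchanged simulated groups sharing controls gave 0.493. With WT libraries split by letter between the comparisons r was 0.375 (SD 0.201 between both ways), which sets the shared deviations of a letter against each other. With KO and WT of one letter against ΔATG and WT of the other, an alternative added after seeing the data, r was 0.595. The covariance less its simulated value was 0.0414, and 1573 genes were higher in both (280 if independent), 1807 lower in both (349) and 52 opposite. In SMADi r was 0.942 (simulated 0.493, split 0.911), the covariance less simulated 0.288, with 4653 higher in both (1136 if independent), 5603 lower in both (1539) and 15 opposite. In Endo r was 0.693 (simulated 0.479, split 0.623), the covariance less simulated 0.0606, with 1376 higher in both (290 if independent), 1667 lower in both (357) and 73 opposite. At day 0, where the controls could not be split, r was 0.518 (simulated 0.489) and the covariance less simulated 0.00823, with 110 higher in both (11 if independent), 287 lower in both (25) and 19 opposite.

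Some genes were lower in an edited line in every setting, that is at day 0 and in all 3 protocols, by at least 2-fold. CHCHD2, a mitochondrial protein gene, had counts of 0 to 2 in the 32 ΔATG libraries, 2138 to 7497 in WT and 962 to 2902 in KO. CEBPZOS, which encodes a small mitochondrial protein, had a median of 0.262 CPM in ΔATG, 24.3 in WT and 22.8 in KO. ZNF354C, a zinc finger gene, had a median of 0.146 CPM in KO, 12.4 in WT and 6.12 in ΔATG, and ZNF229 0.427 CPM in KO and 6.08 in WT. CBR1, a carbonyl reductase, was low in both lines, at a median of 0.886 CPM in KO, 0.565 in ΔATG and 16 in WT. In this way 28 genes were lower and 6 higher in KO, 37 were lower in ΔATG, and 11 lower in both. If the lines were independent 0.04 would be, and 3 simulations of unchanged groups sharing the WT libraries gave 0 genes called alike in both. Neither value can tell a change in both lines from a difference in WT.

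In the overexpression arm the question was what extra lncPRESS1, with or without its start codon, changes against a vector. LNCPRESS1 measured 32.7 ± 0.212 CPM with the vector at the late stage, 152 ± 1.27 with lncPRESS1, 155 ± 0.968 with lncPRESS1 ΔATG and 35.4 ± 0.670 with lncSIRP. At the early stage the libraries labelled lncSIRP had 159 ± 37 CPM and those labelled lncPRESS1 43 ± 15.2, with 29.6 ± 0.839 in the vector and 149.9 ± 8.34 with lncPRESS1 ΔATG, so the target does not bear out those early labels. At the middle stage it measured 42.1 ± 8.15 CPM with the vector, 56.9 ± 2.45 with lncPRESS1, 110.2 ± 31.6 with ΔATG and 13.5 ± 0.224 with lncSIRP. Averaged over the stages as labelled it rose with lncPRESS1 (1.06 ± 0.12, adjusted p = 2.17e-06) and with lncPRESS1 ΔATG (1.99 ± 0.12, adjusted p = 3.01e-09), and was not called with lncSIRP (0.30 ± 0.13, adjusted p = 0.056). With the early labels of lncPRESS1 and lncSIRP exchanged, an alternative added after seeing the data, the averages were 1.69 ± 0.12 with lncPRESS1 (adjusted p = 8.64e-09) and -0.33 ± 0.13 with lncSIRP (adjusted p = 0.0411). Without the early stage they were 1.33 ± 0.15 (adjusted p = 1.01e-06) and -0.76 ± 0.16 (adjusted p = 0.000551), so the direction with lncSIRP rests on the early labels. Leaving out the middle stage instead, they were 1.38 ± 0.15 (adjusted p = 8.05e-05) and 1.27 ± 0.15 (adjusted p = 7.3e-05).

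With lncPRESS1, the middle-stage libraries differed from the vector far more than the others, although LNCPRESS1 itself was not called there (0.44 ± 0.21, adjusted p = 0.0843). POU5F1 at the middle stage measured 265 ± 9.59 CPM against 2262 ± 95.5 with the vector, and SOX2 3.67 ± 0.563 against 255 ± 1.83. HAND1 measured 462 ± 17.5 CPM, CDX2 219.8 ± 3.93 and GATA4 330.1 ± 10.3, against 0.00787 ± 0.0111, 0.0668 ± 0.0168 and 4.29 ± 0.855 with the vector. These libraries have the profile of differentiated cells. Whether they were cultured as the vector was is not given, so the middle-stage difference cannot be assigned to lncPRESS1. At the late stage POU5F1 measured 2478 ± 37.9 CPM against 2201 ± 14.3, and the streak factor EOMES 26.8 ± 7.50 against 8.93 ± 0.377. Averaged over stages, GATA4 (2.74 ± 0.13), the Wnt effector LEF1 (2.72 ± 0.17), TBX3 (2.56 ± 0.20), the protease inhibitor CST1 (3.31 ± 0.13), TMEM88 (2.84 ± 0.19) and MSX2 (3.01 ± 0.18) rose, and the glutamate receptor gene GRIN1 (-5.05 ± 0.55) fell. In the mesoderm list 18 of 24 tested members rose, 1 fell and 5 were not called (18 rose and 1 fell adjusted over the list alone, camera adjusted p = 5.58e-12). In the BMP list 12 of 13 tested members rose and 1 was not called (12 rose adjusted over the list alone, camera adjusted p = 1.01e-07). In amnion and trophoblast 15 of 20 tested members rose and 5 were not called (15 rose adjusted over the list alone, camera adjusted p = 1.05e-09). In the HOX clusters 6 of 19 tested members rose, 1 fell and 12 were not called (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 4.52e-16). In the endoderm list 14 of 20 tested members rose, 2 fell and 4 were not called (15 rose and 2 fell adjusted over the list alone, camera adjusted p = 1.07e-05). Of the pluripotency genes, 2 of 24 tested members rose, 17 fell and 5 were not called (2 rose and 17 fell adjusted over the list alone, camera adjusted p = 2.01e-08, and adjusted p = 0.0823 with an estimated correlation). For Wnt 11 of 14 tested members rose, 1 fell and 2 were not called (11 rose and 1 fell adjusted over the list alone, camera adjusted p = 4.81e-05). These averages rest on the middle stage. Without it 2 of 24 mesoderm genes rose and 1 fell (camera adjusted p = 0.863), 2 of 13 BMP targets rose and 0 fell (camera adjusted p = 0.109) and 3 of 20 genes of amnion and trophoblast rose and 0 fell (camera adjusted p = 0.166). Likewise 0 of 19 HOX genes rose and 0 fell (camera adjusted p = 0.59), 2 of 20 endoderm genes rose and 1 fell (camera adjusted p = 0.526), 3 of 24 pluripotency genes rose and 0 fell (camera adjusted p = 0.526) and 4 of 14 Wnt targets rose and 1 fell (camera adjusted p = 0.0247, 0.25 with an estimated correlation). With the early labels exchanged 11 endoderm genes rose and 4 fell, and camera with an estimated correlation gave an adjusted p = 0.105. As labelled there were 10681 calls, 4992 higher and 5689 lower, with 96 at the early, 13545 at the middle and 5270 at the late stage. The early count carries the doubt about those labels: it was 2511 with them exchanged, and 0 as labelled in a fit of the libraries compared, and the average gave 11339 calls with the labels exchanged. Without the middle stage, an alternative chosen after seeing the data, 3597 genes were called. Without the middle stage TMEM88 (0.57) and MSX2 (0.55) were not called, and the change was 0.97 for GATA4, 0.88 for LEF1, 0.98 for TBX3, 1.29 for CST1 and -2.17 for GRIN1. With the early labels exchanged the change was 1.99 for CST1. Without the early stage the change was 4.56 for MSX2.

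lncSIRP gave a profile close to that of lncPRESS1, with 28 calls between them at late, 510 at middle and 64 at early as labelled. Late changes they share cannot be assigned to extra LNCPRESS1. At the middle stage SOX2 measured 5.33 ± 0.136 CPM and HAND1 338 ± 6.63, and at the late stage EOMES 42.4 ± 8.42. GATA4 (2.97 ± 0.12), LEF1 (2.87 ± 0.15), TBX3 (2.57 ± 0.19) and the kinesin KIF26B (2.56 ± 0.16) rose, and LCK, a kinase gene, fell (-3.57 ± 0.11). Of the mesoderm genes, 15 of 24 tested members rose, 1 fell and 8 were not called (15 rose and 1 fell adjusted over the list alone, camera adjusted p = 9.23e-10). In the pluripotency list 2 of 24 tested members rose, 17 fell and 5 were not called (2 rose and 17 fell adjusted over the list alone, camera adjusted p = 7.32e-07, and adjusted p = 0.114 with an estimated correlation). When the middle stage was left out, 3 of 24 mesoderm genes rose and 3 fell (camera adjusted p = 0.808) and 7 of 24 pluripotency genes rose and 0 fell (camera adjusted p = 0.14). As labelled there were 11680 calls, 5538 higher and 6142 lower, with 2511, 14066 and 4981 at the early, middle and late stage, and 6286 without the middle stage. With the early labels exchanged the average gave 11055 calls and the early stage 96, and in a fit of the libraries compared the early stage as labelled gave 7274. The fold changes of lncPRESS1 and lncSIRP correlated across 13776 genes at r = 0.959, with 0.504 from simulated unchanged groups and 0.926 with split vector libraries, and the covariance less simulated was 0.284. Over the early and late stages r was 0.9, and 0.812 with split vector libraries. Without the middle stage KIF26B (0.34) was not called, and the change was 1.29 for GATA4, 1.27 for LEF1, 1.27 for TBX3 and -0.23 for LCK.

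lncPRESS1 ΔATG lowered streak, endoderm and Nodal genes. EOMES measured 0.165 ± 0.0488, 0.303 ± 0.0953 and 0.272 ± 0.0737 CPM at the early, middle and late stage, against 6.72 ± 0.709, 8.86 ± 1.30 and 8.93 ± 0.377 with the vector. CER1 (-6.15 ± 0.22), EOMES (-5.07 ± 0.22), FOXC1 (-3.34 ± 0.21) and EBF2 (-5.33 ± 0.47) fell. NPTX1 (2.62 ± 0.16), the Wnt antagonist SFRP1 (2.19 ± 0.16), SOX3 (1.63 ± 0.11), EGR1 (1.95 ± 0.17) and CCN2 (1.74 ± 0.12) rose, and POU5F1 measured 1747 ± 161 CPM at the middle stage. In the streak list 14 of 16 tested members fell and 2 were not called (14 fell adjusted over the list alone, camera adjusted p = 2.32e-19). In the Nodal list 10 of 11 tested members fell and 1 was not called (10 fell adjusted over the list alone, camera adjusted p = 3.49e-14). In the endoderm list 3 of 20 tested members rose, 14 fell and 3 were not called (3 rose and 14 fell adjusted over the list alone, camera adjusted p = 4.2e-09). For p53 targets, with GDF15 (-1.36 ± 0.17), 12 of 24 tested members fell and 12 were not called (16 fell adjusted over the list alone, camera adjusted p = 8.51e-06, and adjusted p = 0.0876 with an estimated correlation). In the pluripotency list, with GDF3 (-1.71 ± 0.13) lower, 9 of 24 tested members rose, 7 fell and 8 were not called (10 rose and 8 fell adjusted over the list alone, camera adjusted p = 0.733), and the median (0.13) and mean (-0.08) of the list differed in sign. By exact permutation within stages the streak list changed by -2.73 (exact permutation adjusted p = 0.0233, higher at 0 of 3 stages), where 0.0233 is the smallest adjusted p seen in this arm. There were 6020 calls, 2638 higher and 3382 lower, with 6129, 1714 and 4926 by stage, and 1095 and 335 at the early and middle stage in a fit of the libraries compared. Without the early stage the change was 1.62 for NPTX1.

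Tested directly, the libraries labelled lncPRESS1 with and without its start codon differed for 10715 genes, 5291 higher and 5424 lower in ΔATG, with 3928 calls at the early, 13719 at the middle and 5235 at the late stage, and 4393 without the middle stage. The early count carries the same doubt about labels: with the lncPRESS1 and lncSIRP labels exchanged it was 5881, as labelled in a fit of the libraries compared 3, and the average gave 11135 calls when exchanged. SOX2 was higher with ΔATG (2.26 ± 0.09), and GATA4 (-5.59 ± 0.18), EOMES (-6.19 ± 0.21) and SP5 (-5.72 ± 0.34) were lower. In the streak list 14 of 16 tested members fell and 2 were not called (14 fell adjusted over the list alone, camera adjusted p = 5.07e-12). In the mesoderm list 2 of 24 tested members rose, 17 fell and 5 were not called (2 rose and 17 fell adjusted over the list alone, camera adjusted p = 1.07e-11). Of the pluripotency genes, 20 of 24 tested members rose, 2 fell and 2 were not called (20 rose and 2 fell adjusted over the list alone, camera adjusted p = 2.23e-09). Averaged over the early and late stages, 0 of 16 streak genes rose and 15 fell (camera adjusted p = 6.53e-22), 2 of 24 mesoderm genes rose and 7 fell (camera adjusted p = 0.0554) and 8 of 24 pluripotency genes rose and 8 fell (camera adjusted p = 0.811). For pluripotency with the early labels exchanged, camera with an estimated correlation gave an adjusted p = 0.0676. Against the shared vector the fold changes of both constructs correlated at r = 0.0732 across genes (0.494 simulated, 0.053 with split vector libraries), the covariance less simulated was 0.00704, and 887 genes were higher in both (565 if independent), 1485 lower in both (826) and 1461 opposite. Without the middle stage the change was 0.37 for SOX2.

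**Figure D4:**
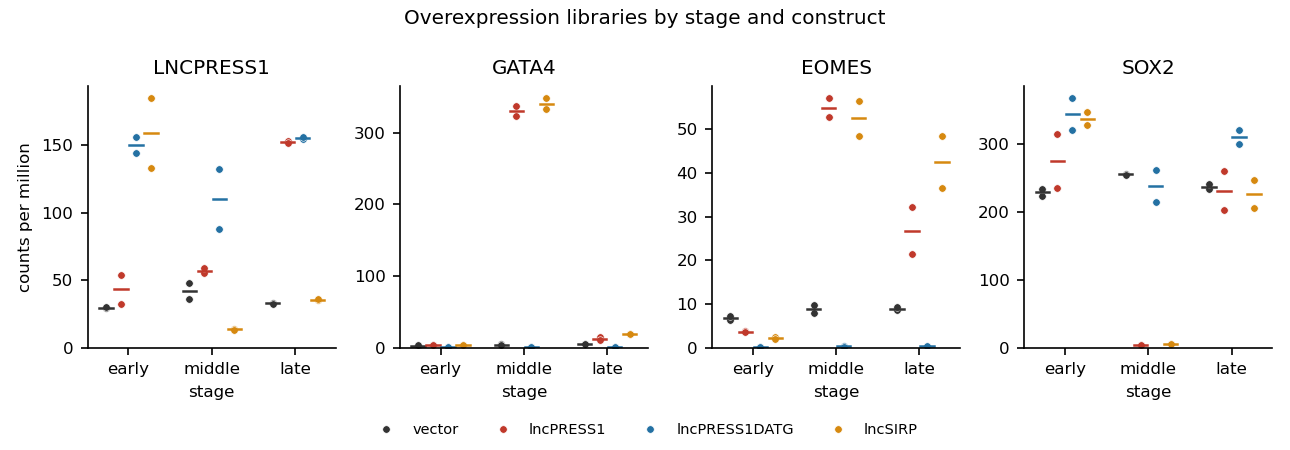
LNCPRESS1, GATA4, EOMES and SOX2 in CPM at the early, middle and late stage for the vector, lncPRESS1, lncPRESS1 ΔATG and lncSIRP, with points for libraries and short lines for group means. SOX2 is near 0 in lncPRESS1 and lncSIRP at the middle stage, and LNCPRESS1 at the early stage is high in the libraries labelled lncSIRP.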

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

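The tests of exchanged early labels, of the 4 readings of the SMADi difference and of a local deletion were chosen only after the results were seen; those of other splits of the libraries and of copy number were chosen before.

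The effect of an edit differed between protocols for many genes, by testing the difference. For KO it differed between BMP4 and SMADi for 10855 genes, between BMP4 and Endo for 5218 and between SMADi and Endo for 7799, and 2954, 725 and 808 of the genes in each pair were called in both protocols with opposite signs. For ΔATG the counts were 9214, 5899 and 9683, with 1557, 691 and 2477 of opposite sign. In KO the pluripotency list lay lower in SMADi than in Endo, relative to WT, by a median of -0.79 (camera adjusted p = 4.09e-14, 0.00938 with an estimated correlation, 17 of 24 members differing on their own), and in ΔATG by -1.22 (camera adjusted p = 6.08e-15, 0.0103 with an estimated correlation, 21 of 24 members differing on their own). In KO the cell cycle list lay higher in BMP4 than in Endo, by 0.21 (camera adjusted p = 4.7e-09, 0.00347 with an estimated correlation, 16 of 23 members differing on their own), and the HOX list lower, by -1.56 (camera adjusted p = 1.1e-06, 0.00401 with an estimated correlation, 1 of 13 members differing on their own). Within a protocol the effect of KO varied over days 1 to 5 for 2684 genes in BMP4, 8432 in SMADi and 762 in Endo, and that of ΔATG for 587, 7610 and 4175. Among the overexpression stages the effect of lncPRESS1 differed for 11237 genes, of lncPRESS1 ΔATG for 3811 and of lncSIRP for 11207.

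At the early stage, LNCPRESS1 was high in the libraries labelled lncSIRP (159 ± 37 CPM) and near the vector in those labelled lncPRESS1 (43 ± 15.2), opposite to the late stage. A rise of LNCPRESS1 alone in the early lncSIRP libraries is argued against: of 27 other genes called between late lncPRESS1 and late lncSIRP, 3.7% had the same sign at early as at late. The reverse held for 96.3% of them, while 92.6% had the same sign at middle as at late; QPCT, for instance, went -3.81 late, -3.10 middle and 3.22 early, and SERPIND1 5.41, 2.94 and -8.36. Exchanged early labels of lncPRESS1 and lncSIRP are a candidate explanation, and early values of these constructs are best read with that in mind. A real change of sign between stages was not tested and stays open.

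In SMADi both edited lines lay far from WT and close to each other, with 275 genes called between them and 11781 and 11660 against WT. WT SMADi day labels out of order are argued against, because the 5 WT groups gave 0 breaks of day order along the path of the edited lines; WT days 3 and 4 tied there, so an exchange of that pair would not show. Such an exchange as the whole cause is argued against by days it does not reach, with 9084 genes called in KO at day 5. Earlier progress of both edited lines along the WT path is possible. At days 3 and 4, 8 of 8 edited libraries correlated best with a later WT day, across genes. In BMP4 19 of 20 and in Endo 20 of 20 matched the same day. SIX3 and ZIC1 were lower in both lines and PAX6 higher, so the same path is not shown. Earlier progress does not account for days 1 and 2 of SMADi, where each edited library matched the same day. At day 1, 2232 genes were called in KO, and day 5 has no later WT day. Another WT cell population in SMADi than at day 0 may also contribute and cannot be told apart: genes at least 2-fold lower in both edited lines at day 0 rose more in WT than in the edited lines from day 0 to day 1, by a median of 0.83, but the quartiles of the 42 genes (-0.87 and 1.94) lie on both sides of 0. A rise of at least 0.5 was also looked for in Endo and not seen (median 0.034), and in BMP4 it was -0.914. The edits, which are confounded with clone, stay open as the biological explanation.

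CHCHD2, CEBPZOS, ZNF354C, ZNF229 and CBR1 were at least 2-fold lower in an edited line at day 0 and in all protocols. The 11 genes lower in both lines cannot be told from a difference in WT. Gain or loss of a whole chromosome is argued against, since 0 chromosomes departed by 0.2 or more in all 4 settings; the largest departure in any setting was 0.0633 in KO and 0.082 in ΔATG, both on chromosome 19. Medians of whole chromosomes do not show a changed segment, which stays open. A local deletion cannot be told apart from other causes: 2 of the 5 genes had a tested neighbour within 500 kb that was at least 2-fold lower in every setting in the same line. PHKG1, 8.57 kb from CHCHD2, had counts of 0 to 5 in ΔATG and 0 to 28 in WT, and ZNF454, 94 kb from ZNF354C, 0 to 18 in KO, 0 to 21 in ΔATG and 21 to 150 in WT. An intronic non-coding gene on the strand of CEBPZOS fell in ΔATG in BMP4 (-3.68), SMADi (-5.21) and Endo (-5.87). It was uncalled at day 0 (-2.38, adjusted p = 0.085). ZNF879, which lies between ZNF354C and ZNF454, had 105 to 565 in KO and 127 to 587 in WT. Deletions within a gene, methylation in the founding clone and an effect of the edit could each give such values and were not tested.

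In a fit of the libraries compared, only the real one of 100 splits gave as many calls in each average. This tests chance between libraries, not between cultures or clones. In BMP4, KO gave 5277 calls and the highest other split 210, ΔATG 2608 and 1522, and ΔATG against KO 1669 and 1251. In SMADi the values were 13164 and 9491 for KO, 12880 and 4720 for ΔATG, and 581 and 151 between the lines. In Endo they were 4879 and 385 for KO, 10212 and 1886 for ΔATG, and 6184 and 2356 between the lines. In the overexpression arm they were 11069 and 10899 for lncPRESS1, 4839 and 2950 for lncPRESS1 ΔATG, 13549 and 12600 for lncSIRP, and 8542 and 7409 for ΔATG against lncPRESS1. In BMP4, where libraries of a letter deviate together, 100 splits that part both letter pairs on each day were compared as well: the highest other than the real one gave 2681 calls for KO, 658 for ΔATG and 819 between the lines.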

How the results depend on the processing

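The averages without the middle or early stage or with exchanged early labels were chosen only after the results were seen. So was the agreement from single letters. Of 161 alternative counts of called genes, leaving aside single libraries left out, 126 were within 1.5 times the reported count. With DESeq2 size factors all 25 counts were, without the low-count filter 22 of 25, with the DESeq2 test 22, with the replicate block 17, with voom 16 and with a fit of the libraries compared 16. Without the early stage all 4 overexpression counts were too, as were the 3 with the early labels exchanged. LNCPRESS1 with lncSIRP changed sign, from 0.30 to -0.76 without the early stage and -0.33 with those labels exchanged. The cause of each difference below was not tested.

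At day 0 KO, ΔATG and ΔATG against KO had 790, 872 and 657 calls without the filter, 77, 248 and 118 with voom, and 3, 2 and 3 in a fit of the 4 libraries compared. Leaving out a library gave 272 to 3262 for KO, 150 to 2392 for ΔATG and 155 to 3476 between the lines. In a fit of the libraries compared, BMP4 had 2608 calls in ΔATG and 1669 between the lines, SMADi 581 between the lines, WT day 5 of BMP4 7504, and dependence on day in BMP4 377 for KO and 20 for ΔATG. With voom SMADi had 693 calls between the lines, and dependence on day 1485 for KO and 281 for ΔATG in BMP4, 11647 for ΔATG in SMADi, and 1429 for KO and 6411 for ΔATG in Endo. With the DESeq2 test SMADi had 462 calls between the lines, and dependence on day 955 for ΔATG in BMP4 and 1370 for KO in Endo. For dependence on day of ΔATG in BMP4, leaving out a library gave 376 to 818. Without the middle stage there were 3597 calls for lncPRESS1, 6286 for lncSIRP and 4393 for ΔATG against lncPRESS1. KO and ΔATG correlated at 0.595 in BMP4 from libraries of one letter each. With control libraries split by letter they did at 0.375 in BMP4, 0.911 in SMADi and 0.623 in Endo. Among constructs r was 0.053 for lncPRESS1 and ΔATG, 0.926 for lncPRESS1 and lncSIRP and 0.0728 for ΔATG and lncSIRP.

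The block for the replicate letter treats a and b as pairs, as the values at day 0 and in BMP4 do and those of SMADi and Endo (residuals of pairs of groups correlated by a median of 0.00659 and -0.00319) do not, and it changed no call of a named gene. With the block, day 0 gave 3188, 2804 and 2661 calls, BMP4 6175 between the lines, and dependence on day 5406 for KO and 1465 for ΔATG in BMP4, and 1763 for KO and 7088 for ΔATG in Endo.

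Of 42 counts for single days or stages, 42 were within 1.5 times with the size factors, 27 with the block and 22 in a fit of the libraries compared. Of 163 gene changes named, 135 were called in every alternative and with each library left out, 28 were lost in at least 1 of them, and 0 changed sign. The lost include all 22 at day 0, none of which was called in a fit of the libraries compared, and 10 of which were not called with voom. Of 220 list calls by camera 93 also held with an estimated correlation and 201 with the block. Of 181 list scores called by permutation, 181 were called with DESeq2 size factors, 171 with a prior count of 0.5 and 180 with 5, and 0 changed direction. All 368 chromosome medians stayed within their spread with the size factors, and the median of all genes shifted by at most 0.022.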

Other observations

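No test was added for this part.

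p53 targets were also lower in other comparisons than those above. In Endo, ΔATG against WT, 12 of 24 tested members fell and 12 were not called (2 rose and 12 fell adjusted over the list alone, camera adjusted p = 0.015, and adjusted p = 0.201 with an estimated correlation), with TIGAR (-0.83 ± 0.16) and SPATA18 (-0.76 ± 0.19). In KO with BMP4, with GADD45A (-0.89 ± 0.05), 10 of 24 tested members fell and 14 were not called (11 fell adjusted over the list alone, camera adjusted p = 0.00354, and adjusted p = 0.0921 with an estimated correlation). By exact permutation within days the p53 score of ΔATG minus WT in BMP4 was -0.54 (exact permutation adjusted p = 0.00167, higher on 0 of 5 days). Without WT day 2 library a SPATA18 (-0.54) was not called.

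Among imprinted genes, H19 fell in ΔATG in BMP4 (-4.09 ± 0.12), where it measured 33.9 ± 2.24 CPM at day 5 against 763 ± 56.2 in WT. MEG3 fell in KO (-2.46 ± 0.19) and ΔATG (-2.58 ± 0.21) in BMP4, and DLK1 fell in Endo in KO (-1.20 ± 0.11) and ΔATG (-0.97 ± 0.10). In the imprinted list of ΔATG in BMP4 1 of 20 tested members rose, 7 fell and 12 were not called (1 rose and 7 fell adjusted over the list alone, camera adjusted p = 0.0286). In Endo 1 of 20 tested members rose, 12 fell and 7 were not called (2 rose and 12 fell adjusted over the list alone, camera adjusted p = 0.00512). Clustered protocadherins fell with overexpressed lncPRESS1 ΔATG, with PCDHGA10 (-2.07 ± 0.10). In that list, 1 of 53 tested members rose, 27 fell and 25 were not called (1 rose and 29 fell adjusted over the list alone, camera adjusted p = 3.94e-09).

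Each list without a result above is given in a single comparison, picked after its values were seen. For oxidative phosphorylation in SMADi, KO against WT, with COX5B (-0.47 ± 0.07), 1 of 23 tested members rose, 19 fell and 3 were not called (1 rose and 19 fell adjusted over the list alone, camera adjusted p = 1.9e-05, and adjusted p = 0.206 with an estimated correlation). For naive and 8-cell-like genes 8 of 11 tested members fell and 3 were not called (8 fell adjusted over the list alone, camera adjusted p = 1.02e-05). For hypoxia, with BNIP3 (-1.38 ± 0.09) and ADM (-1.66 ± 0.18), 1 of 12 tested members rose, 8 fell and 3 were not called (1 rose and 8 fell adjusted over the list alone, camera adjusted p = 0.00494, and adjusted p = 0.184 with an estimated correlation). For immediate early and heat shock genes, with IER3 (-0.84 ± 0.08), 2 of 13 tested members rose, 9 fell and 2 were not called (2 rose and 9 fell adjusted over the list alone, camera adjusted p = 0.00914, and adjusted p = 0.184 with an estimated correlation). For neural crest and placode in Endo, KO against WT, with PAX7 (-1.17 ± 0.14), 5 of 14 tested members fell and 9 were not called (6 fell adjusted over the list alone, camera adjusted p = 0.00619). For Notch targets, with NRARP (-0.60 ± 0.05), 1 of 13 tested members rose, 4 fell and 8 were not called (1 rose and 5 fell adjusted over the list alone, camera adjusted p = 0.00242, and adjusted p = 0.0635 with an estimated correlation). For endothelium and blood in BMP4, ΔATG against WT, with LMO2 (-0.70 ± 0.09), 3 of 12 tested members fell and 9 were not called (3 fell adjusted over the list alone, camera adjusted p = 0.0286). For chromosome 20q11, which is often gained in cultured stem cells, 6 of 21 tested members rose, 1 fell and 14 were not called (8 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0238). For replication-dependent histones at day 0, ΔATG against WT, with H2BC11 (2.02 ± 0.33), 3 of 26 tested members rose and 23 were not called (5 rose adjusted over the list alone, camera adjusted p = 0.165). H2BC11 was not called in a fit of the libraries compared. Without ΔATG library a H2BC11 (0.91) was not called.

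Within groups the libraries a and b correlated across genes at r from 0.9752 to 0.9899, and 0 pairs of libraries were identical.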
